A study of Homo sapiens with 5 samples.

How the data were processed

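Poly(A) RNA of Ishikawa cells was sequenced in 5 libraries: 2 of co-culture with adipocytes, 2 of co-culture with EX527 and 1 of monoculture. Per the labels' protocols and the series' design text, 500 ng of total RNA per sample went through poly(A) enrichment and a library kit that is not described as marking strand, with 12 PCR cycles and Illumina HiSeq sequencing. Reads left after removal of ribosomal RNA were mapped to GRCh38.p7 with STAR v2, per the same text. FastQC, MultiQC, fastp, featureCounts and DESeq2 are named in the submitters' processing notes, without versions. The annotation, the strand setting of the counting and the treatment of overlapping genes are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Antisense genes held 5.03% to 5.48% of reads.

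The authors deposited a table of raw counts per gene (57992 genes) and a table of normalized signal, which is those counts divided by 1 size factor per library. The deposited factors were 0.953 and 1.05 for co-culture, 1.14 and 1.00 for EX527 co-culture and 0.876 for monoculture, equal to DESeq2's median-of-ratios factors computed from the counts. Total counts were 48549180 and 52269963 reads in co-culture, 46792566 and 45653845 with EX527 and 46226566 in monoculture. At these depths 3 reads correspond to 0.0574 to 0.0657 CPM, and such floors cover counting error only, since PCR copies are not independent molecules. Both co-culture libraries differed by more than sampling noise (mean chi-square per gene 5.95 over 26474 genes with 20 reads or more in both together) and were counted as 2 samples.

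Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10), scaled by TMM and fitted with 1 coefficient per group over all 5 libraries, which leaves 2 residual degrees of freedom. The quasi-likelihood F-test was run with the edgeR 4 dispersion estimate, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The installed version's default is the older estimate, and a first look at the data was made with that default before the planned setting was run. The planned setting is the one reported, and the older one is an alternative. Log2 CPM used a prior count of 2, and fold changes are on the log2 scale.

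The samples' groups, tests, alternatives not named as later ones, named-gene rule and 31 gene lists were fixed before the data were examined. The lists held 826 genes, of which 786 matched a gene in the table by symbol or older symbol. They covered pathways and markers of adipocytes and of fibroblasts and preadipocytes. Lists were tested with camera in limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The estimated form rests on the 2 residual degrees of freedom of the fit, so a list it does not call may still have changed. The preset form gives p-values that are too small where the genes of a list are correlated above 0.01. List medians are of log2 CPM differences. Gene positions come from GENCODE 44 on GRCh38, which may differ from the authors' annotation.

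Genes named in the text followed that fixed rule. It took SIRT1, then per direction the 8 largest changes among called genes of both main comparisons and the 4 largest of the third. Those needed a mean log2 CPM of at least 2, libraries that do not overlap between groups and an official symbol. Where none was called, as here, it took the 4 genes with the smallest p per direction, as values. Of each list called by camera it took up to 3 members with the smallest p.

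The tests across genes were checked on simulated counts with the real means and library sizes, with 200 genes changed. With the spread of all 5 libraries, EX527 against co-culture recovered 4.48% of 67 genes changed 2-fold, 65.7% of 67 changed 4-fold and 95.5% of 66 changed 8-fold, out of 32092 genes tested. Co-culture against monoculture recovered 1.49%, 38.8% and 87.9% out of 32111 genes tested. EX527 co-culture against monoculture recovered 0, 47.8% and 80.3% out of 32230. In that order of comparisons 3, 3 and 10 unchanged genes were called. Each gene was drawn with the same spread in all libraries. The real replicate pairs differed unequally, with an SD of the log2 difference of 0.112 in co-culture and 0.605 with EX527 at well-read genes. The recovery rates may therefore not hold for the real fit. In it DHRS2, changed 30.6-fold, and MEOX1, changed 21.2-fold, were not called for EX527 against co-culture (edgeR adjusted p = 0.0751). With the spread left without EX527 co-culture replicate 1, 100% of changed genes were recovered at each fold, apart from 98.5% at 2-fold in co-culture against monoculture, and 12, 13 and 6 unchanged genes were called out of 30451, 30604 and 30574. These simulations still drew and fitted all 5 libraries, with the same common dispersion for every gene. They therefore do not describe the fits with a lone EX527 library, which may vary more.

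Alternatives were other scalings, filters, dispersion estimates and tests (DESeq2 1.42.0, limma-voom, limma-trend on the authors' normalized values, a minimum fold of 1.5), subsets of groups, replicate blocks, and each replicated library left out in turn. Leaving out the monoculture library ends both comparisons with it and was not run. Some results on single genes are not reported here. Figures were drawn with matplotlib 3.10.9.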

Results

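The data were gene counts from 5 poly(A)-selected RNA-seq libraries of Ishikawa cells, an established human line of endometrioid endometrial cancer. In 2 libraries the cells had been cultured for 3 days below differentiated adipocytes, with a membrane of 0.4 µm pores between both cell types. In 2 more the co-culture contained EX527, an inhibitor of the deacetylase SIRT1, at a dose the labels do not give. The remaining library came from cells grown alone, so monoculture has n = 1. Libraries held 45653845 to 52269963 counted reads, and 34658 of 57992 genes passed the filter on low counts. The comparisons addressed what differs in these cancer cells with co-culture and with EX527 added to it. No library came from monoculture with EX527. An effect of EX527 through the adipocytes, or one unrelated to co-culture or to SIRT1, therefore cannot be told apart from SIRT1 inhibition in the cancer cells. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

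Replicates of both co-culture groups differed from each other to unequal degrees. At the 11232 genes with a mean log2 CPM of at least 4, the SD of the log2 difference between both co-culture libraries was 0.112, against 0.605 between both EX527 co-culture libraries. EX527 co-culture replicate 1 had 33325 genes with 10 reads or more, where the other 4 libraries had 26022 to 27103, and long intergenic RNAs took 2.66% of its reads, against 1.36% to 1.49% elsewhere. The common dispersion was 0.264 with all 5 libraries, 0.00434 without EX527 co-culture replicate 1 and 0.0045 without replicate 2. Leaving out either EX527 library leaves the co-culture pair to set the spread, so this fall does not single out replicate 1. Each comparison is given with all 5 libraries, as planned, and then without EX527 co-culture replicate 1. In the second form the spread comes from the co-culture pair alone, and the lone EX527 and monoculture libraries are assumed to vary like that pair. When either co-culture library was left out, the EX527 pair alone set the spread and the common dispersion was 0.456.

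SIRT1, the target of the inhibitor (chromosome 10, 67884656 to 67918390, GRCh38), was read at 30.3 and 32.9 CPM in co-culture, 26.2 and 29.7 CPM with EX527 and 42.7 CPM in monoculture. The log2 fold change of EX527 against co-culture was -0.18 (SE 0.20, edgeR adjusted p = 0.597), and it became 0.09 when only library size was used for scaling. Against monoculture, SIRT1 differed by -0.43 in co-culture (SE 0.24, edgeR adjusted p = 0.479) and by -0.61 with EX527 (SE 0.24, edgeR adjusted p = 0.614). Both of the latter passed without EX527 co-culture replicate 1, at -0.48 (adjusted p = 7.64e-06) and -0.57 (adjusted p = 1.74e-05), and without replicate 2, at -0.48 (adjusted p = 0.000137) and -0.70 (adjusted p = 3.78e-06).

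The G2/M and G1/S lists had negative medians in co-culture with EX527 against co-culture without it, and neither was called by camera with an estimated correlation (adjusted p = 0.639 for each). All 32 genes of the G2/M list fell when adjusted over the list alone, with a median log2 fold change of -1.76. HMMR, a spindle protein, was read at 112 and 112 CPM in co-culture and at 18.1 and 18.8 CPM with EX527 (log2 fold change -2.60, SE 0.19). HMMR is uncertain in so far as reads were shared with its antisense gene HMMR-AS1, itself at 53.5 and 58.0 CPM in co-culture. Cyclin B1 (CCNB1), which drives entry into mitosis, went from 368 and 363 CPM to 82.3 and 91.4 CPM, and the topoisomerase TOP2A from 510 and 545 CPM to 151 and 150 CPM. Of 30 G1/S genes, 13 fell when adjusted over the list alone (median -0.82), among them RRM2, a subunit of ribonucleotide reductase (-2.49, SE 0.25), and the replication factor CDC45 (-1.68, SE 0.20). When either co-culture library was left out, 29 G2/M genes still fell over the list alone, while the G1/S count went from 13 to 0 without co-culture replicate 1 and to 1 without replicate 2. It was 24 lower and 1 higher when EX527 co-culture replicate 1 was left out, and 26 lower and 2 higher when replicate 2 was. The medians of both lists were -1.57 and -0.61 without EX527 co-culture replicate 1.

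The hypoxia, ATF4 and NF-kB lists had positive medians with EX527. In the hypoxia list 16 of 24 genes rose when adjusted over the list alone and none fell (median 0.94). Adrenomedullin (ADM) was read at 12.9 and 13.3 CPM in co-culture and at 72.1 and 51.7 CPM with EX527, and the angiogenic factor VEGFA at 157 and 155 CPM and at 378 and 562 CPM. In the ATF4 list of amino acid stress genes 8 of 27 rose and 1 fell when adjusted over the list alone (median 0.41). The stress transcription factor ATF3 had a log2 fold change of 3.01 (SE 0.34), and DDIT3, which encodes CHOP, one of 2.45 (SE 0.24). In the NF-kB and inflammatory list 2 of 27 rose and 1 fell when adjusted over the list alone (median 0.96). Its member with the largest fold, TNF, stayed at 0.0899 and 0.0821 CPM in co-culture and at 1.98 and 1.02 CPM with EX527, and TNFAIP2 was lower, at -2.13 (SE 0.41). No gene of these 3 lists passed over the list alone when either co-culture library was left out. With EX527 co-culture replicate 1 left out the medians were 1.06 for hypoxia, 0.71 for ATF4 and 0.75 for NF-kB genes, and over the list alone 24, 21 and 12 genes rose and 0, 3 and 2 fell. With replicate 2 left out instead, 19, 12 and 16 rose and 3, 8 and 5 fell. An estimated correlation ended all 3 camera calls (adjusted p = 0.639, 0.80 and 0.639).

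The epithelial, interferon and mitochondrial lists had negative medians with EX527. Of 26 epithelial markers 10 fell and 1 rose when adjusted over the list alone (median -0.93), and keratin 18 (KRT18) went from 1194 and 1066 CPM to 226 and 288 CPM. KRT18 and KRT19 have processed pseudogenes, so their counts are uncertain as far as reads were shared. Of 31 interferon genes 14 fell when adjusted over the list alone (median -0.76), with IFI6 at -2.68 (SE 0.31) and BST2 at -1.88 (SE 0.24). Of 13 genes encoded by the mitochondrial genome 11 fell when adjusted over the list alone (median -1.83), and their share of reads was 4.99% and 5.20% in co-culture, 1.19% and 2.47% with EX527 and 1.90% in monoculture. Mitochondrial genes have nuclear copies, which makes these counts uncertain in the same way. Among cholesterol synthesis genes 1 of 25 fell when adjusted over the list alone (median -0.51). With all 5 libraries no fatty acid synthesis gene of 18 passed over the list alone (median -0.66). Its member SREBF1, the lipogenic transcription factor, was read at 383 and 354 CPM in co-culture and at 41.5 and 106 CPM with EX527. Histone genes had a median of -0.96, with 4 of 12 lower over the list alone. Markers of adipocytes and of fibroblasts and preadipocytes were not called (camera adjusted p = 0.176 and 0.0803). Over the list alone 3 of 20 adipocyte markers rose, and 2 of 20 fibroblast and preadipocyte markers rose and 1 fell. These counts were 12 higher with 5 lower and 13 higher with 3 lower without EX527 co-culture replicate 2, 5 higher with 1 lower and 5 higher with 3 lower without replicate 1, and none when either co-culture library was left out. Their medians were 0.54 and 1.09 with all libraries and 0.08 and -0.01 without EX527 co-culture replicate 1. The epithelial count over the list alone went from 10 lower to 4 without co-culture replicate 1 and to 6 without replicate 2, and the interferon, mitochondrial, cholesterol and histone counts went to 0 in both cases. When EX527 co-culture replicate 1 was left out, 16 epithelial, 17 interferon, 13 mitochondrial, 17 cholesterol, 11 fatty acid synthesis and 7 histone genes fell over the list alone, and 7 epithelial, 2 interferon and 2 fatty acid synthesis genes rose. When replicate 2 was, 19 epithelial, 20 interferon, 13 mitochondrial, 20 cholesterol, 14 fatty acid synthesis and 7 histone genes fell, and 3 epithelial, 5 interferon, 2 cholesterol and 1 fatty acid synthesis genes rose. Leaving out EX527 co-culture replicate 1 gave medians of -0.45 for epithelial, -0.85 for interferon, -1.16 for mitochondrial, -0.38 for cholesterol, -0.35 for fatty acid synthesis and -0.62 for histone genes. With an estimated correlation none of these 6 lists was called (adjusted p = 0.639 to 0.675).

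Those 11 lists were the ones called by camera with its preset correlation, 3 upward and 8 downward (adjusted p from 1.43e-21 for G2/M genes to 0.0192 for ATF4 genes). With an estimated correlation none of the 31 lists was called (smallest adjusted p = 0.639). That form rests on 2 residual degrees of freedom, so its failure to call a list decides little. Even G2/M genes, all 32 of them lower, had an unadjusted camera p of 0.0667 in it. The smallest there was 0.0350, for interferon genes. The preset form has a limit too, since it assumes a correlation of 0.01. Estimates were 0.274 for G2/M, 0.433 for G1/S and 0.971 for mitochondrial genes, but -0.013 for interferon and -0.028 for NF-kB genes. Where the true correlation is that high, the preset p-values are too small. The ATF4 call was lost without co-culture replicate 2 (adjusted p = 0.143) and without EX527 co-culture replicate 2 (adjusted p = 0.600), and the NF-kB call without the latter (adjusted p = 0.211). The other 20 lists, such as glucocorticoid response, p53 targets, sirtuins and NAD metabolism and ribosomal proteins, gave adjusted p-values of 0.0551 to 0.930.

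No single gene passed an adjusted p of 0.05 over all genes in this comparison. The edgeR quasi-likelihood test gave a smallest adjusted p of 0.0751, with 6702 of 34658 genes under an unadjusted 0.05, where chance alone gives 1733. The DESeq2 Wald test called 3510 genes (2052 higher, 1458 lower), and limma-voom 0, with 5266 under an unadjusted 0.05. Leaving out EX527 co-culture replicate 1, edgeR called 13001 genes (6370 higher, 6631 lower), among them all 24 hypoxia genes as higher and all 32 G2/M genes as lower. Without EX527 co-culture replicate 2 it called 24078 (13405 higher, 10673 lower), with 18 hypoxia genes higher and 3 lower, 12 ATF4 genes higher and 8 lower, and all 32 G2/M genes lower. As values, the genes with the smallest p were STK32A at 4.15 (SE 0.25), the DNA damage gene GADD45A at 3.26 (SE 0.20), the lysosomal protein LAMP3 at 4.23 (SE 0.28) and NIBAN1 at 3.37 (SE 0.23). In the other direction they were the homeobox gene MEOX1 at -4.41 (SE 0.22), the dehydrogenase DHRS2 at -4.93 (SE 0.27), the decoy receptor IL1R2 at -3.45 (SE 0.23) and FOLH1 at -3.37 (SE 0.24), all with an edgeR adjusted p of 0.0751. Scaling by library size alone moved the median log2 fold change of all genes from 0.15 to 0.42, and the called lists kept their directions under it.

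**Figure D1:**
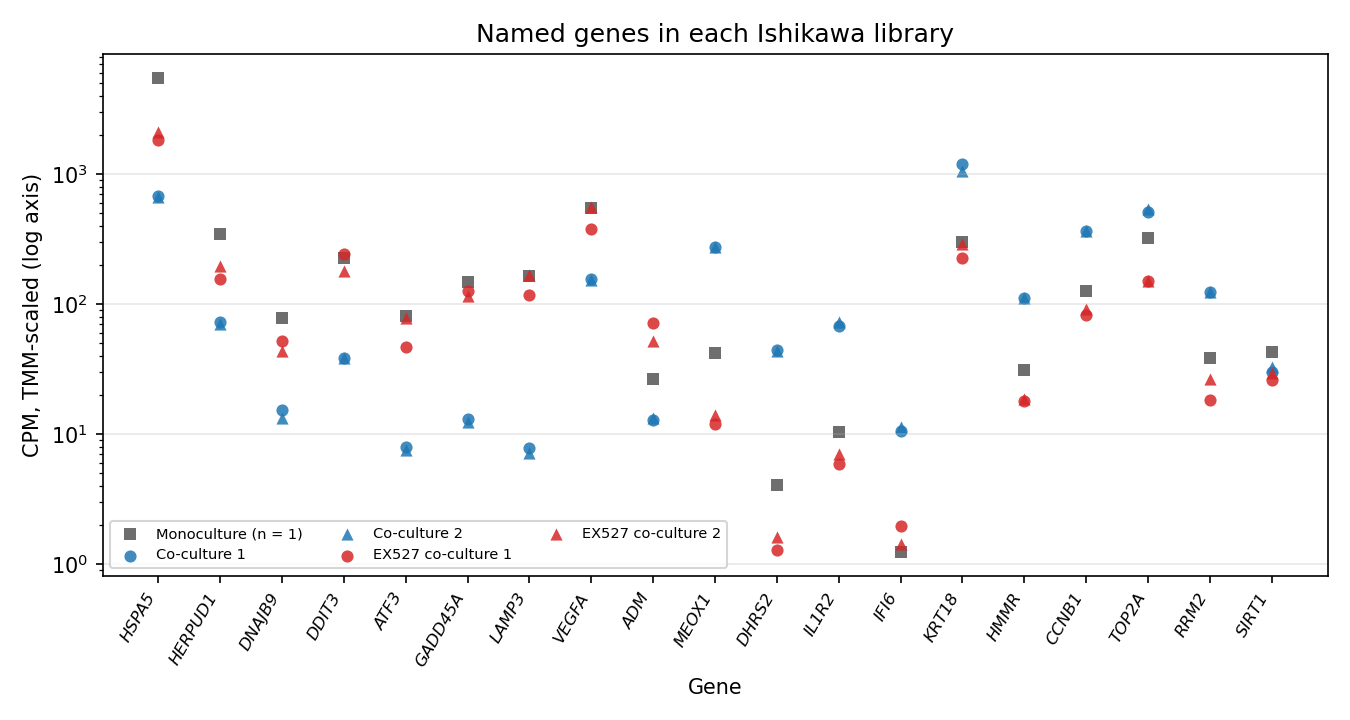
TMM-scaled CPM (log axis) of 19 named genes, 1 point per library, for monoculture (n = 1), co-culture (n = 2) and EX527 co-culture (n = 2). Both co-culture libraries lie outside the range of the other 3 for each gene drawn except SIRT1, as for HSPA5 (681 and 666 CPM in co-culture, 1826 and 2101 CPM with EX527, 5529 CPM in monoculture).

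Co-culture with adipocytes was set against the single monoculture library. The unfolded protein response, ATF4, hypoxia, immediate early and estrogen lists had negative medians in co-culture. In the unfolded protein response list 8 of 21 genes fell when adjusted over the list alone and none rose (median -0.78). The chaperone BiP (HSPA5, chromosome 9, 125234853 to 125241382, GRCh38) was read at 681 and 666 CPM in co-culture and at 5529 CPM in monoculture (log2 fold change -3.04, SE 0.22). DNAJB9, an endoplasmic reticulum co-chaperone, differed by -2.47 (SE 0.25) and HERPUD1, which serves protein degradation at that membrane, by -2.27 (SE 0.23). In the ATF4 list 11 of 27 genes fell and none rose (median -0.74), including ATF3 (-3.39, SE 0.37) and DDIT3 (-2.54, SE 0.26). In the hypoxia list 7 of 24 fell (median -0.63), including VEGFA (-1.82, SE 0.29) and ERO1A (-1.23, SE 0.21). Of 30 immediate early genes 10 fell (median -0.37), with FOSL1 at 0.337 and 0.37 CPM against 7.28 CPM. Of 28 estrogen response genes 7 fell (median -0.48), and the progesterone receptor PGR was at 0.27 and 0.164 CPM against 6.27 CPM. These counts are adjusted over the list alone. The unfolded protein response count went from 8 to 3 without co-culture replicate 1 and to 0 without replicate 2, and the other 4 counts went to 0 in both cases. Leaving out either EX527 library instead, 15 unfolded protein response, 22 ATF4, 20 hypoxia, 19 immediate early and 14 estrogen response genes fell, and 2, 4, 2, 5 and 4 rose. With an estimated correlation none of these 5 lists was called (adjusted p = 0.653, and 0.663 for immediate early genes). Heat shock and NRF2 genes were not called with the preset one either (camera adjusted p = 0.353 for each), although over the list alone 1 of 18 heat shock genes fell, and 8 of 30 NRF2 genes fell and 2 rose. The NRF2 counts were 14 lower and 11 higher and the heat shock counts 10 lower and 5 higher when either EX527 library was left out, and 0 when either co-culture library was.

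The interferon, cell cycle and mitochondrial lists had positive medians in co-culture, and few or none of their genes passed a test of their own. Of 31 interferon genes 7 rose when adjusted over the list alone and none fell (median 1.39), with IFI6 at 10.6 and 11.3 CPM against 1.24 CPM. All 32 G2/M genes had a positive log2 fold change (median 0.73), and 4 rose when adjusted over the list alone, with HMMR at 1.84 (SE 0.24) and CCNB1 at 1.52 (SE 0.23). Of 30 G1/S genes 3 rose when adjusted over the list alone (median 0.73), and CDC45 had a value of 1.76 (SE 0.26). All 13 mitochondrially encoded genes had positive values (median 1.26) and none passed over the list alone. The histone list had a median of 0.62 with none passing. No gene of these 5 lists passed over the list alone when either co-culture library was left out. When either EX527 library was, 19 interferon, 29 G2/M, 26 G1/S, 13 mitochondrial and 6 histone genes rose over the list alone, and 2 G1/S genes fell, with 3 interferon genes lower without replicate 1 and 1 without replicate 2. Nor were these 5 lists called with an estimated correlation (adjusted p = 0.653 for each).

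Camera called these 10 lists with its preset correlation, 5 in each direction (adjusted p from 9.81e-07 to 0.0423), and none of 31 with an estimated correlation (smallest adjusted p = 0.653). The histone call was lost without co-culture replicate 1 (adjusted p = 0.137) or replicate 2 (adjusted p = 0.0509), and the immediate early call without EX527 co-culture replicate 2 (adjusted p = 0.0592). The remaining 21 lists gave adjusted p-values of 0.0669 to 0.861, adipocyte markers at 0.462 and fibroblast and preadipocyte markers at 0.0669 among them.

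Over all genes, edgeR called 0 genes between co-culture and monoculture (smallest adjusted p = 0.118), with 5526 of 34658 under an unadjusted 0.05. DESeq2 called 2483 (962 higher, 1521 lower) and limma-voom 0, with 4848 under an unadjusted 0.05. With EX527 co-culture replicate 1 left out, edgeR called 15861 genes (7904 higher, 7957 lower), with 29 of 32 G2/M genes and all 13 mitochondrially encoded genes higher, and 15 of 21 unfolded protein response genes lower. Without EX527 co-culture replicate 2 it called 15300 (7592 higher, 7708 lower), with the same 3 counts for these lists. The genes with the smallest p, given as values, were DHRS2 (3.44, SE 0.32), MEOX1 (2.70, SE 0.26), IL1R2 (2.75, SE 0.29) and the amino acid transporter SLC6A20 (2.48, SE 0.28) on the higher side. On the lower side they were the microtubule protein MAP1B (-3.43, SE 0.21), GADD45A (-3.54, SE 0.22), NIBAN1 (-3.64, SE 0.25) and LAMP3 (-4.46, SE 0.31), each with an edgeR adjusted p of 0.118. The test rests on the assumption that monoculture varies like the replicated groups.

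**Figure D2:**
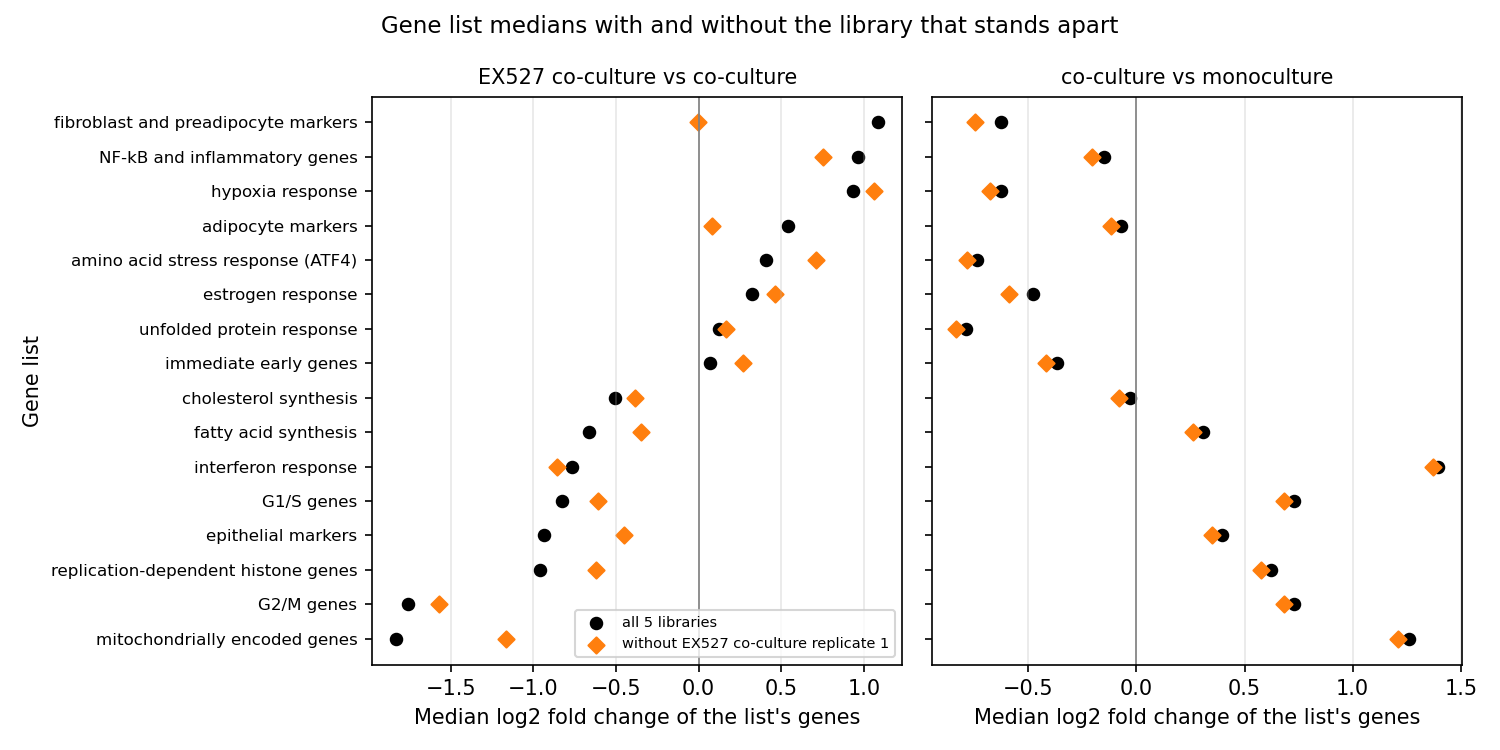
Median log2 fold change of each called gene list and of the adipocyte and fibroblast marker lists, in both comparisons, with all 5 libraries (black) and without EX527 co-culture replicate 1 (orange). G2/M genes had medians of -1.76 and -1.57 for EX527 against co-culture, and the fibroblast and preadipocyte list went from 1.09 to -0.01.

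EX527 co-culture was also set against monoculture, which shows where the co-culture with EX527 stood relative to cells grown alone. Of 32 G2/M genes 17 fell when adjusted over the list alone (median -0.87), and the list was not called with an estimated correlation (adjusted p = 0.718). Its member DLGAP5, a spindle protein, was read at 18.1 and 26.1 CPM against 73.3 CPM. Of 25 cholesterol synthesis genes 6 fell when adjusted over the list alone (median -0.69), with HMGCS1 at 94.6 and 85.2 CPM against 207 CPM. Of 21 unfolded protein response genes 4 fell when adjusted over the list alone (median -0.72), with HSPA5 at -1.49 (SE 0.22). All 3 counts went to 0 when either co-culture library was left out. They were 32, 19 and 18 lower without EX527 co-culture replicate 1, with 0, 3 and 1 higher, and 32, 22 and 19 lower without replicate 2, with 0, 1 and 0 higher. Fatty acid synthesis (median -0.62), heat shock (median -0.43), NRF2 (median -0.34), insulin and FOXO (median -0.42), epithelial (median -0.48), p53 (median -0.41), ATF4 (median -0.33) and immediate early genes (median -0.48) were the other lists called by camera, all downward. With an estimated correlation none of the 31 lists was called (smallest adjusted p = 0.718). The mean fitted log2 fold change of the insulin and FOXO list was 0.08, opposite in sign to its median. The epithelial, p53, ATF4 and immediate early calls were lost without EX527 co-culture replicate 1 (adjusted p = 0.214, 0.350, 0.594 and 0.243). The 20 lists not called had adjusted p-values of 0.0712 to 0.909.

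By edgeR 0 genes passed between EX527 co-culture and monoculture (smallest adjusted p = 0.614), with 2555 under an unadjusted 0.05. DESeq2 called 60 genes and limma-voom 0, with 2034 under an unadjusted 0.05. After EX527 co-culture replicate 1 was left out, edgeR called 9927 genes (4317 higher, 5610 lower), and without replicate 2 it called 21330 (11449 higher, 9881 lower). Scaling by library size alone moved the median of all genes from 0.21 to 0.46. The genes with the smallest p, as values, were the phosphatase DUSP15 (4.11, SE 0.37), the presynaptic protein PCLO (3.14, SE 0.37), the lipase inhibitor ANGPTL4 (3.08, SE 0.44) and DCXR (1.60, SE 0.25). MEOX1 (-1.71, SE 0.23), HSPA5 (-1.49, SE 0.22), the cell cycle inhibitor CDKN1C (-1.92, SE 0.29) and the co-chaperone DNAJB4 (-1.42, SE 0.22) had the smallest p on the lower side.

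Across genes, the change with EX527 and the change with co-culture ran in opposite directions. Pearson's r between both log2 fold changes was -0.548 and Spearman's rho -0.537 over 34658 genes, which are not independent replicates, and 71.5% of genes had opposite signs. Co-culture libraries enter both comparisons with opposite sign, and 100 simulations without any effect gave a mean r of -0.408. They gave all libraries the same spread per gene, estimated from both replicate pairs. The co-culture pair itself differed less than the EX527 pair (SD 0.112 against 0.605 at genes with a mean log2 CPM of at least 4). The simulated covariance may therefore overstate what sharing gives. The covariance was -0.662, against a simulated mean of -0.309 and a simulated lowest of -0.325, a difference from the mean of -0.352. With 1 co-culture library in each comparison, so that none was shared, r was -0.466 and -0.406. A deviation that both co-culture libraries have in common is not removed by this split. At the 11232 genes with a mean log2 CPM of at least 4, r was -0.795, where the simulations gave -0.408. Of genes under an unadjusted 0.05 in both comparisons 3047 had opposite and 11 equal directions. In 20 simulations without any effect the mean counts were 260 and 4.65, and independent lists give 535 and 533. No gene passed the adjusted threshold of edgeR in either comparison. Part of the negative r may come from the shared libraries, which the simulations already contain. The value of r was -0.638 without EX527 co-culture replicate 1 and -0.395 without replicate 2.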

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

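The crossed replicate block, the fits of the relation without 1 library or with EX527 replicate 2 alone, and the lists without mitochondrially encoded genes were chosen after seeing the data. For EX527 against co-culture, where 0 genes passed, upper-quartile scaling called 69, a stricter filter 353, the older dispersion estimate 21, limma-trend on the authors' values 414 and DESeq2 3510. The replicate block called 867 (368 higher, 499 lower). Deviations of same-numbered libraries correlated at -0.120 (-0.363 at genes with a mean log2 CPM of at least 4), which gave no sign of pairing. With EX527 co-culture replicate 1 apart from the other libraries, these correlations cannot exclude pairing. A crossed replicate block called 3382. Leaving out 1 library gave 0 to 24078 genes. For co-culture against monoculture DESeq2 called 2483, the co-culture and monoculture libraries alone 15889, and leaving out 1 library gave 0 to 15861. For EX527 co-culture against monoculture DESeq2 called 60, and leaving out 1 library gave 0 to 21330. Each count of 0 among these came from leaving out a co-culture library, which leaves the EX527 pair to set the spread. Calls with 1 EX527 library rest on the co-culture pair, whose dispersion was 0.00434 or 0.0045. For the other changes the cause was not tested. All other settings called 0 genes. SIRT1 ranged from -0.50 to -0.37 in co-culture and from -0.70 to -0.57 with EX527 against monoculture when 1 library was left out, and passed (-0.48 and -0.48, -0.57 and -0.70) where an EX527 library was out. With an estimated correlation 0 lists were called in each comparison. The relation of both changes had r = -0.406 with co-culture replicate 2 alone against monoculture, -0.795 at genes with a mean log2 CPM of at least 4, -0.383 with edgeR's default prior count, and -0.638 to -0.395 with 1 library left out. Of the values for named genes, 530 kept their side of the threshold, 351 came to pass it and none reversed past it. Changes of sign without a pass were not counted, such as that of SIRT1 in EX527 against co-culture with library size alone. Of the values for called lists, 189 kept their call and 44 lost it.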

Other observations

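The tests of the GC content and length trend, of genomic DNA, of adipocyte RNA, of shared libraries and of mitochondrial reads were written before their results were seen, and the test of 5' ends only after antisense genes over 5' ends had been noticed as low in the library it concerns.

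Glucocorticoid response genes were split in EX527 co-culture against co-culture. Of 26 genes 8 rose and 3 fell when adjusted over the list alone, while the list as a whole was not called (camera adjusted p = 0.0551). With an estimated correlation the adjusted p was 0.639. With the preset correlation it was 0.0146, upward, without EX527 co-culture replicate 1 and 0.211 without replicate 2. Over the list alone 3 rose and 2 fell when either co-culture library was left out, 15 rose and 6 fell without EX527 co-culture replicate 1, and 17 rose and 6 fell without replicate 2. TIPARP had a log2 fold change of 2.73 (SE 0.33). CRISPLD2 was read at 29.8 and 31.7 CPM in co-culture, 7.24 and 7.07 CPM with EX527 and 10.8 CPM in monoculture. Among adipocyte markers, PPARG, the regulator of fat cell differentiation, was at 7.40 and 6.90 CPM in co-culture, 18.6 and 25.9 CPM with EX527 and 42.7 CPM in monoculture, so its transcript was present without co-culture too. These 3 genes were singled out after their values were seen. In co-culture against monoculture, 9 of the 26 glucocorticoid response genes fell and 1 rose over the list alone (camera adjusted p = 0.0876). Per the labels, the adipocytes of both co-culture groups had been differentiated with 0.5 µM dexamethasone, 5 µg/ml insulin and 0.5 mM IBMX. Whether any of these reached the Ishikawa cells was not tested.

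EX527 co-culture replicate 1 stood apart from the other 4 libraries. Human RNA of mature adipocytes as the whole cause is argued against. The highest of ADIPOQ, FABP4 and PLIN1 was 3.08 CPM there before TMM scaling, for PLIN1, which was at 3.14 CPM in monoculture. ADIPOQ (1.09 CPM) and FABP4 (0.727 CPM) were still highest in that library, so a trace stays open. Reads of another species stay open too, since the adipocytes' species is not given. RNA of undifferentiated cells among the adipocytes is not covered by these 3 genes and stays open. For EX527 against co-culture, the fibroblast and preadipocyte median given above was positive with this library and slightly negative without it. Genomic DNA as a part stays open: olfactory receptor genes, normally silent in such cells, were 2.66 times the highest of the other libraries, between the bounds of 2 and 4 set for a decision, but only 142 of 356 had a read, and their 0.0484 CPM per kb of exon lay below those of 4 gene classes picked as near silent in the other libraries, of which the lowest had 0.0788, where even coverage gives equal values. Loss of transcript 5' ends, as in degraded RNA, stays open too. The median log2 difference between antisense genes over 5' and over 3' ends against replicate 2 was -0.62. Its bootstrap 95% interval, resampled over genes, was -0.86 to -0.48. This difference concerns a class in which low genes had already been seen and so decides nothing. A real difference between both EX527 cultures was not tested.

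The EX527 and co-culture changes ran opposite across genes. EX527 co-culture still differed from monoculture in value, with a G2/M median of -0.87 and HSPA5 at -1.49 (SE 0.22), and an effect of EX527 itself, which the design names, stays open. Noise particular to each shared library, as the whole cause, is argued against by r = -0.406 where none was shared. A covariance below all 100 simulated ones argues against it too. If both co-culture libraries came from the same culture, which the labels do not exclude, its deviation would enter both comparisons. Neither the split nor the simulations can decide on that, and it stays open. A GC content or length trend is argued against by r = -0.408 after its removal, where no library was shared. A batch common to both co-culture libraries cannot be told apart from co-culture itself, because the labels give no batch and both libraries form that group.

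The unfolded protein response, ATF4 and hypoxia lists had negative medians in co-culture against the single monoculture library, and none of them was called with an estimated correlation (adjusted p = 0.653 for each), while heat shock and NRF2 genes were not called with the preset one either (adjusted p = 0.353 for each). Over the list alone 8 NRF2 genes fell and 2 rose, as against 8 lower and none higher in the unfolded protein response list. After removal of a GC content and length trend the median of the unfolded protein response list was -0.61 (bootstrap 95% interval -1.31 to -0.25). Without mitochondrially encoded genes it was -0.84 (-1.27 to -0.23). The first median argues against a GC content and length trend as the whole cause. Mitochondrially encoded genes held 4.99% and 5.20% of reads in co-culture and 1.90% in monoculture. Shares this small can hardly move other genes, so the second median was nearly fixed beforehand and adds little. The shares themselves argue against mitochondrial reads as the whole cause. The intervals resample the genes of the list and do not measure the spread between cultures. A medium or density difference of the monoculture culture may act in the same way as adipocytes do and stays open with n = 1, as does the effect of adipocytes itself.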
